A study of Mus musculus with 8 samples.

How the data were processed

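RNA was measured in peritoneal macrophages from wild-type mice and from mice labelled Zc3h12a-/-. Per the labels' protocols, the cells came from mice injected with thioglycollate, an irritant that draws macrophages into the peritoneal cavity. They were stimulated with 100 ng/ml of lipopolysaccharide (LPS), the bacterial cell wall component sensed through TLR4, for 0, 1, 2 or 4 h. RNA was extracted with Trizol and biotinylated cRNA was made with the NuGEN Ovation system, per the labels' protocols. Each of the 8 samples was hybridised to 1 Affymetrix array, which gave 1 array for each genotype and time.

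The deposited table holds log2 values for 45101 probe sets on each of the 8 arrays. The submitters' processing notes name RMA, a method that corrects background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a probe set on the log2 scale. Its version is not given in the sources used here. The column medians lay between 3.14 and 3.21. Quantile normalization assumes that most genes do not change, so a change in total mRNA between times would not be seen in these values, and up and down counts depend on that assumption. All 8 value columns were used.

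Probe sets were named from the platform annotation given with the table. Of them, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here. The Entrez identifiers of 34754 single-symbol probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Control probe sets and those without a single symbol were left out. Each gene was represented by its probe set of highest mean over the 8 arrays. A gene was kept when its second-highest array was at or above 3.16, the median of all values in the table. This kept 12540 of 18193 genes.

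Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with time as a block, which left 3 residual degrees of freedom. The same additive fit gave 1, 2 and 4 h of LPS against 0 h with genotype as a block. A further fit asked whether the genotype difference after LPS departed from that at 0 h, with 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Errors are limma's moderated standard errors (SE). The genotype difference at a single time rests on 2 arrays, so it was given as a value without a test. The fits were tested on simulated data for the 12540 genes, with 100 genes changed by 1 log2 unit and 100 by 2. The genotype comparison recovered 99 and 100 of them, with 7.44% of its calls false, and the test of a changed genotype difference recovered 24 and 100, with 8.82% false. The LPS comparisons recovered 91, 92 and 95 of the 100 changed by 1 unit at 1, 2 and 4 h, and 100 of those changed by 2. The list test called a shifted list and 0 of 25 unshifted ones. In these simulations the spread was independent between genes and each change was of 1 size at all its times, as the fits assume. The shares recovered and false need not hold for the real arrays.

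A set of 29 gene lists was fixed before the data were examined. The 25 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. An estimated correlation and fry were the alternatives. For single times, a list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Counts "adjusted over the list alone" use the list's own p-values.

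The highest of 27 probe sets for bacterial control transcripts gave each array's background, between 2.96 and 3.26. This rule was chosen after seeing the data. A gene at or below it on every array of a group has only a bound there. It is given as "at least", from the brighter group's mean and the dimmer group's mean with each array at no less than its background. The number of arrays limits the precision.

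The rule for named genes, fixed before the data were examined, took Zc3h12a on every probe set, then the 12 genes of largest positive and the 12 of largest negative genotype difference past the threshold with 1 sign at all 4 times. It took the 8 largest increases and 4 largest decreases at each LPS time and the 4 members of smallest p in each list. For the changed genotype difference it took the 3 genes of smallest p each way when none passed. Without a test it took the 10 genes of highest and the 5 of lowest mean difference over 1, 2 and 4 h. Il6, Il12b, Tnf, Il1b, Il10, Calcr and Nfkbia were always included. Other genes named were chosen after their values were seen, and the text says so.

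Alternatives fixed in advance were cyclic loess between arrays, centring on a housekeeping list, no filter, a filter at the 75th percentile, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, eBayes with trend and robust settings, an added 2-fold minimum, other sample choices and leaving out each array. The labels do not say how many mice were pooled or whether cultures were separate. The p-values therefore measure only the spread between these arrays, which may be technical.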

Results

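Gene expression was profiled in thioglycollate-elicited peritoneal macrophages from wild-type mice and from mice labelled Zc3h12a-/-, before and 1, 2 and 4 h after LPS. Zc3h12a encodes Regnase-1, an RNase that degrades inflammatory mRNAs such as Il6. The 8 arrays comprised 1 for each genotype and time, so no group had a replicate. The pairwise correlations of the arrays lay between 0.899 and 0.984. The 3' minus 5' difference of the Gapdh control probe sets lay between 2.90 and 3.31 on the log2 scale. Between 79.9% and 96.3% of tested genes lay above background. All 8 arrays carried Xist at 10.95 or above.

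The targeted gene was examined first. The brighter of the 2 Zc3h12a probe sets read 6.12, 8.02, 8.87 and 8.57 at 0, 1, 2 and 4 h in wild-type cells. It read 6.73, 7.70, 8.75 and 8.50 in the cells labelled knockout. The other probe set stayed between 3.01 and 3.31 on all arrays. Neither was lower in the labelled-knockout arrays beyond the spread between arrays. The position of these probe sets relative to the deleted part of the gene is not known here, so they check nothing about the labels. The arrays are called labelled knockout throughout, and every direction below rests on the label.

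The first comparison asked which genes differed between genotypes on average over the 4 times, which need not be a difference at each time. Retnla, which encodes a secreted resistin-like protein, was 27.2-fold higher (log2 difference 4.76, SE 0.08, adjusted p = 2.5e-06). Chil3, a chitinase-like protein, was 14.6-fold higher and Ccl24, an eosinophil-attracting chemokine, 17.6-fold higher. The neuropeptide gene Npy was at background in all 4 wild-type arrays and at least 203-fold higher in the labelled-knockout arrays (adjusted p = 4.8e-07), and Rnase2a, a secreted ribonuclease, differed by 7.12 (SE 0.12). The differences were 4.43 (SE 0.18) for Ccn3, 4.38 for Vmn2r26, 3.68 for Ighm (the IgM heavy chain, with at least 7.32 by the probe set that lay furthest apart), 3.58 for Cd55 and 3.31 (SE 0.11) for Cadps2. Sprr2d and Sprr2f were also among the 12 largest, with differences of 6.04 (SE 1.31) and 5.09 (SE 1.21), but at 0 h they differed by only 0.56 and 0.37. Their adjusted p-values of 0.033 and 0.042 were lost, at up to 0.115 and 0.139, without any single array of 1, 2 or 4 h, and at 0.135 and 0.156 with trend and robust settings.

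Among the genes lower in the labelled-knockout arrays, Hal, which encodes histidine ammonia-lyase, differed by -5.49 (SE 0.12), from a wild-type mean of 9.94 to 4.45. Gdpd3, a phosphodiesterase, differed by -5.19 (SE 0.09). The interferon-inducible Ifi27l2a differed by -4.09 (SE 0.25) and Gdf3, a TGF-beta family ligand, by -3.96 (SE 0.20). Zmynd8 differed by -2.85, the peptide transporter gene Slc15a2 by -2.73, the cell cycle inhibitor gene Cdkn1c by -2.57 and Arsb, a lysosomal sulfatase, by -2.52. The collagen gene Col6a2 differed by -2.42, Clu (clusterin) by -2.36, Pawr by -2.31 and Bex1 by -2.29. All 12 passed the threshold, and none of these calls was lost when any single array was left out.

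**Figure D1:**
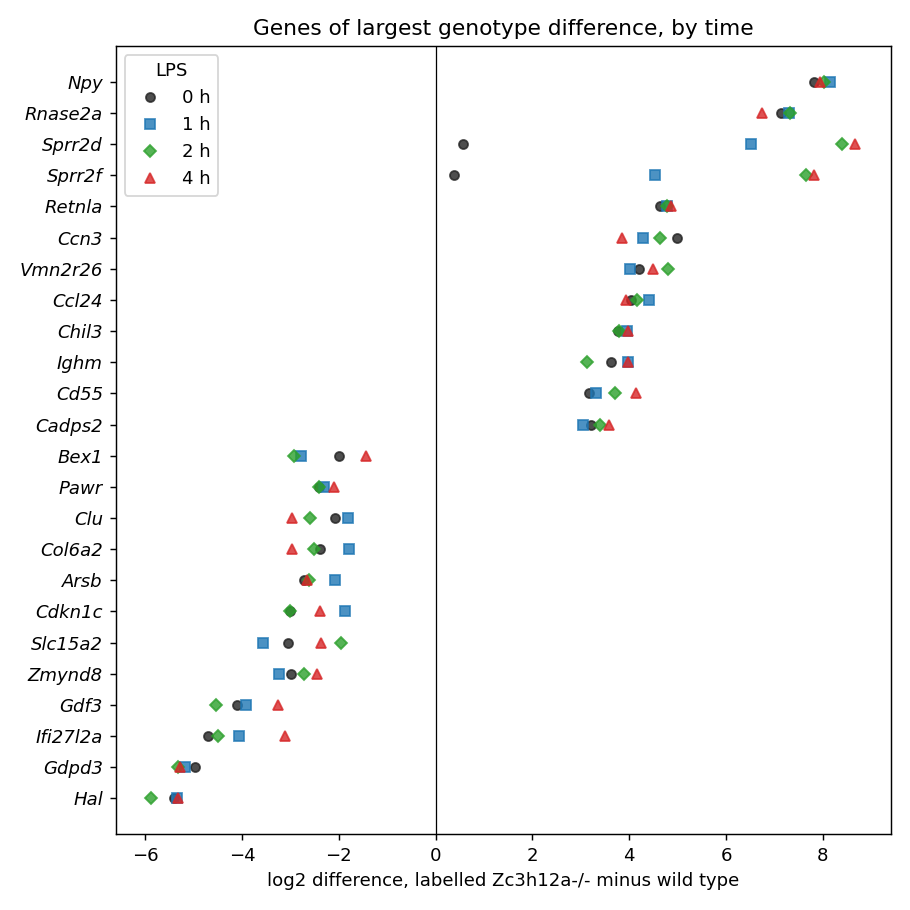
Log2 difference between the labelled-knockout and the wild-type array at each time (x axis, log2 units) for the 24 genes of largest genotype difference (y axis), with 1 symbol per time. Most genes differ by a like amount at all 4 times, whereas Sprr2d and Sprr2f differ by 0.56 and 0.37 at 0 h and by 8.67 and 7.81 at 4 h. At 4 h Sprr2f was below the background of the wild-type array (3.02), so its value there is only a difference of readings.

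By limma with time as a block, 1690 of 12540 genes differed between genotypes, 596 higher and 1094 lower in the labelled-knockout arrays. Of them, 333 differed at least 2-fold, 185 higher and 148 lower, and 1688 had 1 sign at all 4 times. After cyclic loess the split was 773 higher and 777 lower, and after centring on the housekeeping list 654 higher and 865 lower. The count was 150 without the time block. It was 597 without either 0 h array, 700 without either 2 h array and 942 without either 4 h array, since leaving out 1 array of a time removes that time from the comparison. Between single times, the differences correlated across genes with Pearson r from 0.586 to 0.720 and, by rank, Spearman values from 0.340 to 0.572. Genes are not independent replicates. The 3' minus 5' difference of the Actb control probe sets, a measure of RNA quality, was higher in the labelled-knockout array at each of the 4 times. It was 3.11, 2.61, 2.52 and 2.30 at 0, 1, 2 and 4 h, against 2.64, 2.35, 2.43 and 2.16 in wild type. That of Gapdh was higher at 0 h (3.31 against 3.01) and lower at 1, 2 and 4 h (2.95, 3.04 and 2.90 against 2.99, 3.16 and 2.98).

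Of the gene lists, that of resident peritoneal macrophage markers showed the clearest difference. All 10 measured members had positive differences and 9 rose past the threshold (also 9 when adjusted over the list alone). Prg4, a lubricating proteoglycan, was higher by 3.29 (SE 0.10), the lipoxygenase gene Alox15 by 2.88 (SE 0.22), the B cell attractant Cxcl13 by 1.53 (SE 0.08) and Fabp7 by 1.34 (SE 0.08). The list's median was 1.75 (camera adjusted p = 5.6e-12; adjusted p = 0.162 with an estimated correlation). In the same arrays 7 of 9 measured mesothelial and stromal markers fell and 0 rose (also 7 and 0 adjusted over the list alone). Col1a1 and Col1a2, the type I collagen genes, fell by 1.53 and 1.77, Sparc by 1.85 and Bgn by 1.04 on the log2 scale. That list's median was -1.04 (adjusted p = 2.6e-06; adjusted p = 0.162 with an estimated correlation). Of 19 general macrophage markers 2 rose and 1 fell (2 and 1 adjusted over the list alone), and that list missed the threshold (adjusted p = 0.758).

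Alternative activation markers were also higher as a list, with 8 of 14 measured members rising and 2 falling (9 and 3 adjusted over the list alone). Besides Retnla, Chil3 and Ccl24, Arg1, which encodes arginase-1, rose by 2.72 (SE 0.11). The 2 that fell were Pparg, a lipid-sensing nuclear receptor gene (-1.28), and the scavenger receptor gene Stab1 (-1.16), named after their values were seen. The list's median was 0.72 (adjusted p = 2.6e-06; adjusted p = 0.523 with an estimated correlation). Of 13 MHC class II and costimulation genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). H2-Eb1 rose by 0.88, Cd86 by 0.95 and Cd74 by 0.55, while Icosl fell by 0.79 on the log2 scale (list adjusted p = 0.0035; adjusted p = 0.575 with an estimated correlation). Resident macrophage markers and the Actb 3' minus 5' difference were higher in the same arrays.

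Of 23 chemokine genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone). Ccl24 and Cxcl13 belong to the lists above as well. Ccl17 rose by 2.01 (SE 0.41) and Ccl8 by 0.35 (SE 0.07), but the call of Ccl17 was lost without either 0 h or either 1 h array (adjusted p up to 0.112) and with trend and robust settings (0.0917), and that of Ccl8 without any 1 of the 8 arrays (up to 0.113). The list's median was only 0.07 (adjusted p = 0.0123; adjusted p = 0.612 with an estimated correlation). Of 13 measured mRNAs reported as Regnase-1 targets, 2 rose and 0 fell (3 and 0 adjusted over the list alone). Tfrc, the transferrin receptor gene, rose by 1.32 (SE 0.09) and Icos by 1.29 (SE 0.17). Some of these targets were chosen in work on such samples, so the list is not independent evidence of a direction. Its median was 0.19 (adjusted p = 0.0187; adjusted p = 0.575 with an estimated correlation). At 0, 1, 2 and 4 h the median of reported targets was 0.44, 0.12, 0.34 and -0.02. The value at 4 h lay at percentile 67.3 of the random lists. The chemokine median at those times was 0.38, 0.13, 0.05 and 0.01, with percentile 82.1 at 4 h. Both medians were thus highest before LPS and near 0 at 4 h. Without either 0 h array the adjusted p was 0.0944 for chemokines and 0.121 for reported targets.

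**Figure D2:**
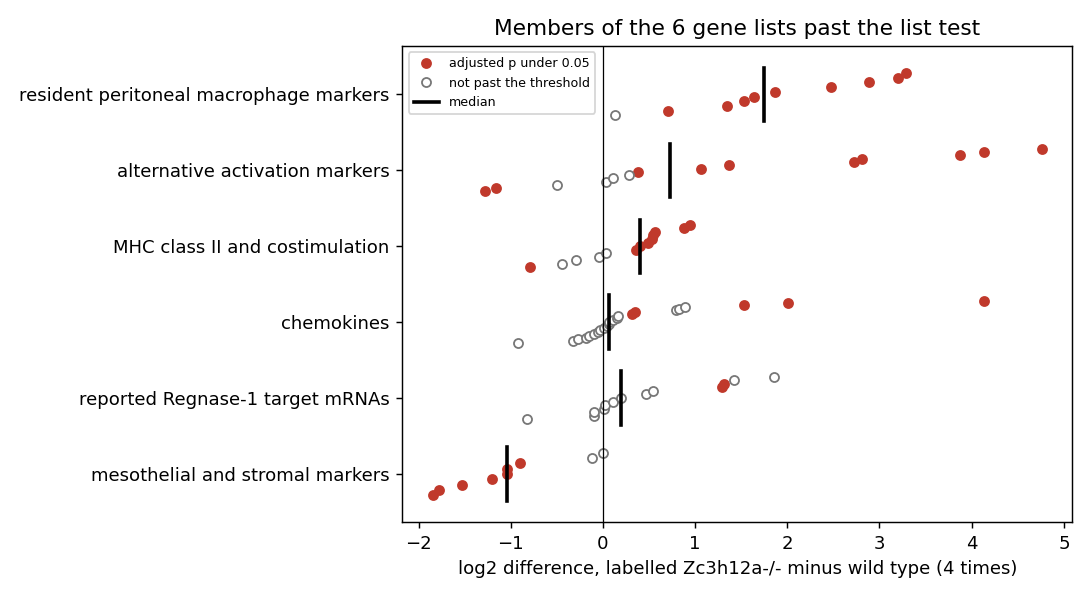
Log2 difference between genotypes over the 4 times (x axis, log2 units) for each measured member of the 6 gene lists past the list test (y axis). Filled points passed adjusted p 0.05 over all genes, open points did not, and bars mark list medians, from -1.04 for mesothelial and stromal markers to 1.75 for resident peritoneal macrophage markers.

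The second comparison asked how LPS changed expression over time, with both genotypes together. At 1 h, Il1b rose by 8.77 (SE 0.15), Tnfsf9 by 8.45 (SE 0.18), Tnf from 5.70 to 12.56 in wild type and from 5.48 to 12.62 in labelled knockout, and the prostaglandin synthase gene Ptgs2 by 7.15 (SE 0.38). The chemokine genes Cxcl10, Cxcl1 and Ccl4 rose by 6.84, 6.72 and 6.60, and Il6 by 6.53 (SE 0.69). Zfp763, Snhg10, Chchd7 and E330020D12Rik fell by 3.07, 2.80, 2.71 and 2.63 on the log2 scale, but Snhg10 differed by only -0.11 (adjusted p = 0.773) without probe sets that can match several transcripts. Immediate early genes, the first to respond to a stimulus, rose in 23 of 27 cases, and NF-kB targets and feedback regulators in 18 of 19. Both counts were 23 and 18 adjusted over the list alone. Of 21 inflammatory cytokines 13 rose (15 adjusted over the list alone). Nfkbia, which encodes an NF-kB inhibitor, rose by 2.41 (SE 0.11).

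At 2 h, Cxcl3, at background in both 0 h arrays, rose by at least 6.71 on the log2 scale, and the interferon-induced Mx1 by 6.89 (SE 0.15), after a difference of -0.51 at 1 h (adjusted p = 0.0827). All 33 measured interferon-stimulated genes rose at 2 h and at 4 h, against 10 rising and 1 falling at 1 h. Adjusted over the list alone, 13 rose and 2 fell at 1 h and 33 rose at 2 and 4 h. The list's median was 0.20 at 1 h (adjusted p = 0.101 with an estimated correlation), 2.86 at 2 h and 4.41 at 4 h. By 4 h, Ifit3, Ifit1bl1 and Ifit2 rose by 8.03, 7.78 and 7.63, and the long RNA U90926 by 7.63. Cxcl10 reached 9.24 (SE 0.14) above 0 h. Among decreases, Thbd, the anticoagulant receptor thrombomodulin, fell by 4.52 at 2 h and 5.96 at 4 h, and Fbxo32 by 4.83 and 4.90. Tifab, at background in both 2 h arrays, fell at 2 h by at least 4.18 and Hhex by 4.44, and Mxd4 and Zdhhc14 by 4.93 and 4.92 at 4 h, all on the log2 scale. Immediate early genes had a median of 2.46 at 1 h, 0.70 at 2 h (adjusted p = 0.165 with an estimated correlation) and 0.18 at 4 h (adjusted p = 0.321 with an estimated correlation). Of the reported Regnase-1 targets, 8, 10 and 10 of 13 rose at 1, 2 and 4 h (9, 10 and 10 adjusted over the list alone). At 4 h 1 fell (also 1 adjusted over the list alone). With an estimated correlation their adjusted p was 0.0711, 0.137 and 0.214.

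The Actb 3' minus 5' difference was lower at 1, 2 and 4 h than at 0 h in both genotypes. By limma, 1313 genes changed at 1 h (483 higher), 5239 at 2 h (1499 higher) and 5498 at 4 h (1809 higher). The split depends on scaling. After cyclic loess, 618, 2330 and 2606 genes were higher and 439, 2296 and 2665 lower, and after centring on the housekeeping list 741, 4228 and 8001 were higher and 355, 1777 and 1245 lower. That centring moved the median of all genes at 4 h from -0.12 to 0.62. The housekeeping genes themselves had a median of -0.32 at 4 h, with 6 of 12 falling in the deposited values. The count at 1 h ranged from 454, without the wild-type 0 h array, to 1086 when arrays were left out. It was 501 without the wild-type 1 h array, 559 without the labelled-knockout 0 h array and 810 without the labelled-knockout 1 h array. At 2 h it was 3141 without the wild-type 0 h array, 3375 without the labelled-knockout 0 h array and 3206 without the labelled-knockout 2 h array. By camera, 13, 11 and 10 lists shifted at 1, 2 and 4 h. At 1 h the call of CCCH zinc finger and mRNA decay factors was lost without the wild-type 0 h array (adjusted p = 0.124) and that of MHC class II genes without the labelled-knockout 1 h array (0.0536). With an estimated correlation 3, 2 and 2 lists passed. At 1 h these were inflammatory cytokines, immediate early genes and NF-kB targets (adjusted p = 0.0289 for each), and at 2 and 4 h inflammatory cytokines and interferon-stimulated genes (adjusted p = 0.0272 and 0.0451 for each).

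The third comparison asked whether the genotype difference itself changed with LPS, the question the role of Regnase-1 in mRNA decay raises. Il6 read 7.97, 10.06 and 11.49 at 1, 2 and 4 h in wild type and 11.50, 12.52 and 12.49 in the labelled-knockout arrays. The 2 arrays of 0 h differed by 0.42, but the wild-type reading lay below its array's background. That value is only a difference of readings, so the Il6 difference without LPS could not be measured. The brighter Il12b probe set lay below background in both 0 h arrays, with the same limit. Il12b was lower in the labelled-knockout arrays after LPS, with 8.30 and 8.62 in wild type at 2 and 4 h against 6.98 and 7.09, and its second probe set differed in the same direction. Calcr, the calcitonin receptor gene, read 5.19 and 5.91 at 2 and 4 h in the labelled-knockout arrays and 3.01 and 2.66 in wild type, where it was at background at all 4 times (at least 2.16-fold over the 4 times, adjusted p = 0.137). Il10 read 7.21 in wild type and 4.37 in labelled knockout at 1 h, and 4.89 and 4.80 at 4 h. Tnf differed by -0.18 (SE 0.09) and Il1b by -0.06 (SE 0.10) over the 4 times, neither past the threshold. The single-time differences have no replicate check. Over the 4 times Il6 differed by 1.85 (SE 0.49, adjusted p = 0.057) and Il12b by -0.82 (SE 0.25, adjusted p = 0.085). The SE of that test includes any change of the difference with time, so a missed threshold is not evidence of no difference after LPS. Over 21 alternatives the adjusted p of Il6 lay between 0.0489, without probe sets that can match several transcripts, and 0.967, without the time block. That of Il12b lay between 0.0487, with trend and robust settings, and 0.995, without the time block. Each passed under that 1 alternative only.

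Sprr2d and Sprr2f, which encode small proline-rich proteins of epithelial barriers, lay far apart between genotypes after LPS. Sprr2d read 9.49, 11.88 and 11.79 at 1, 2 and 4 h in the labelled-knockout arrays, against 2.97, 3.48 and 3.12 in wild type. Sprr2f read 7.83, 10.92 and 10.76 against 3.31, 3.26 and 2.95. Olr1, a receptor for oxidised lipoprotein, was already at 10.76 without LPS in labelled knockout, against 7.05 in wild type, and the difference at 4 h was 0.74. Id3 read 8.17 at 1 h in wild type and 6.25 in labelled knockout, after 5.40 and 5.44 at 0 h.

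**Figure D3:**
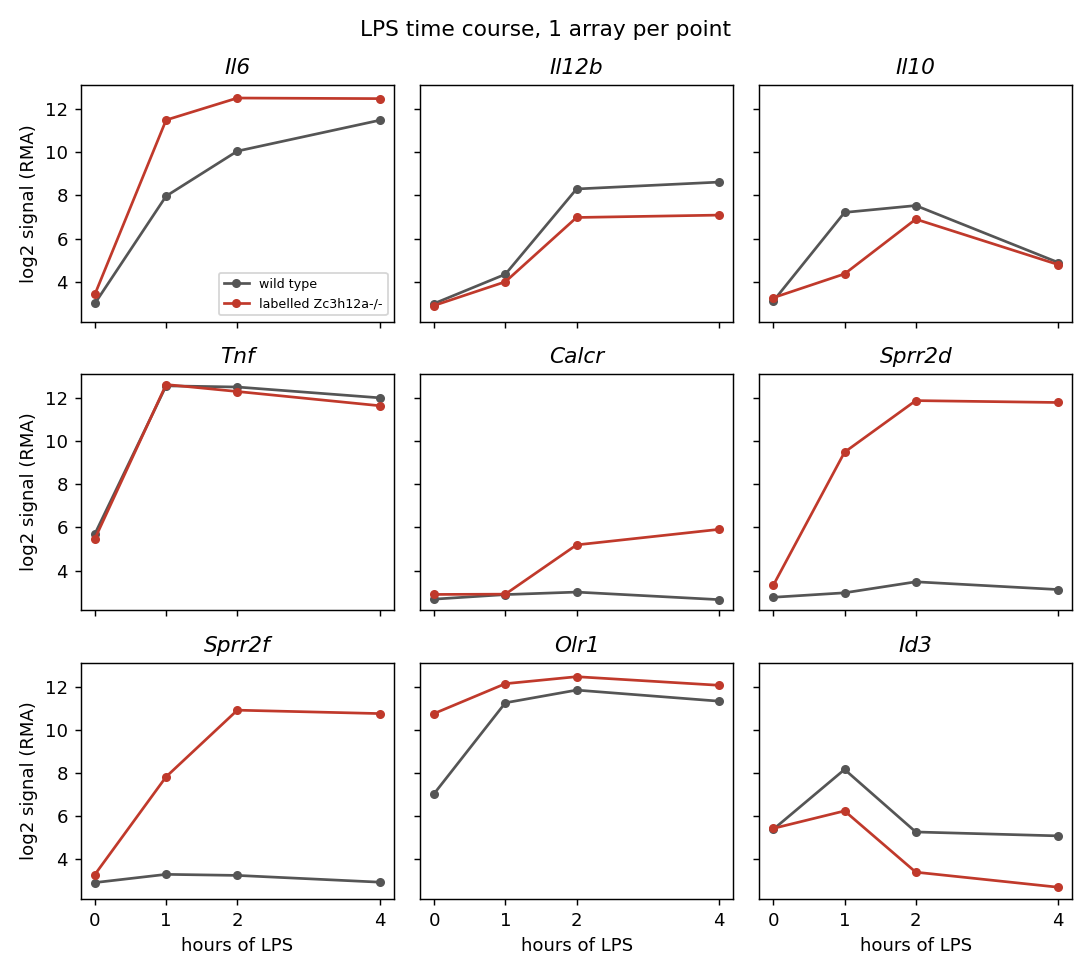
Log2 signal (y axis) against hours of LPS (x axis) for 9 genes, with 1 array per point and a line for each genotype. Il6, Sprr2d and Sprr2f lie higher in the labelled-knockout arrays at 1, 2 and 4 h and Calcr at 2 and 4 h, Il12b and Id3 lie lower, and Tnf nearly coincides.

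By limma, 0 genes passed the test of a changed genotype difference, and 434 had an unadjusted p under 0.05 where 627 would by chance. A difference that varied among 1, 2 and 4 h counted as error here, and 121 genes with an estimate of 2-fold or more did not pass. The 0 calls thus exclude no change of that size. With trend and robust settings in eBayes 15 genes passed, 4 upward and 11 downward. Among them were Olr1 and, chosen after their values were seen, Acod1 (-1.17) and Nfkbiz (-1.33). Without either 1 h array 6 passed, with Sprr2d at 7.97 and Sprr2f at 7.36 (adjusted p = 0.00122 for each). The fit without a 0 h array could not be made. The smallest p-values belonged upward to Sprr2d (7.30, SE 0.86), Pheta2 (1.68) and Mras (1.13) and downward to Olr1 (-2.97, adjusted p = 0.278), Id3 (-2.10) and U90926 (-1.89), none past the threshold. Without a test, 474 genes were at least 2-fold apart at 0 h, 422 at 1 h, 603 at 2 h and 486 at 4 h. Of these, 261, 253, 247 and 210 were higher in the labelled-knockout arrays. With the mean of all probe sets of a gene the counts were 295, 269, 351 and 306.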

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

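All tests of explanation in this part were chosen after the result they measure was seen.

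Among the named genes, 7 moved one way in every wild-type array after LPS and the opposite way in every labelled-knockout array. All changes of a genotype are taken from its single 0 h array, so that reading alone can set every sign without any response to LPS. The difference was not tested beyond the interaction test, in which no gene passed. Labelled knockout minus wild type, as the mean change from 0 h over 1, 2 and 4 h, was -0.73 for Ccn3, 1.23 for Cpa3, 0.36 for Fcmr, 0.21 for Npy, -0.66 for Saa3, 0.37 for Siglech and -0.23 for Xist. Fcmr was at background on all labelled-knockout arrays and Npy on all wild-type arrays, and Siglech lay between 2.99 and 3.53 throughout.

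Probe sets without a single gene symbol were not used in the comparisons. Of 10092 such probe sets, 12 were at least 2-fold higher and 4 at least 2-fold lower in the labelled-knockout arrays at all 4 times. The brightest of 3 probe sets named with Igkc, shared by several immunoglobulin kappa genes, was higher by 2.49 on average. It read 9.80 (SD 0.33 over the 4 times) against 7.31 (SD 0.37 over the 4 times) in wild type, and the 4 times are not replicates.

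This kappa signal goes with Ighm (3.68, SE 0.15) and Jchain (2.89, SE 0.22), the heavy chain of IgM and the chain that joins IgM units. A single cross-hybridising probe set is argued against, since 6 of 11 Ighm probe sets were at least 2-fold higher at all 4 times, by 3.68 to at least 7.32 on average, while 3 of the other 5 were at background on all arrays and 2 differed by -0.55 and 1.15. Of the 6, all except the probe set furthest apart are of the kind that can match several transcripts. They are not independent, and a match shared with related transcripts is not excluded. Mature B cells are argued against as well: without Ighm the B cell list had a median of -0.44, 0 of its other members rose, and Cd79a read 3.29 in labelled knockout against 3.62. Plasma cells may be a source and are not excluded: 2 of 4 measured plasma cell markers rose, but 1 was Jchain itself and the call of the other, Igha, was lost without any 1 of 6 arrays (adjusted p up to 0.122) and with the mean of all probe sets (0.0649), Sdc1 fell by 1.02 from a high macrophage level and 4 genes decide nothing. A difference between the mice that the genotype names was not tested.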

How the results depend on the processing

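The alternatives were fixed before the data were examined. Over 486 named-gene results, 7631 of 8238 comparisons with an alternative counted as the same, 492 lost the call, 112 gained it and 3 reversed. Results past the threshold in the main fit counted as the same if they kept their direction and call. For the others, a change of sign also counted as the same. Genotype fits without either array of a time, or without both, are 1 fit, so the comparisons are not independent. The 3 reversals were at 4 h of LPS after centring on the housekeeping list, with 0.21 for Rpl13a, 0.050 for Cma1 and 0.12 for Batf3, where the centring adds to every gene. It also gave 9246 genes at 4 h. Adding a 2-fold minimum, which can only lower a count, left 333 genes between genotypes and 542, 2025 and 2570 at 1, 2 and 4 h of LPS. Genotype counts were 150 without the time block and 597 at the 3 stimulated times, with fewer arrays. Leaving out 1 array or 1 time pair gave 597 to 1237 genes between genotypes, and leaving out 1 array gave 454 to 1086, 3141 to 5248 and 3951 to 5425 at the LPS times. Of the 1690 genes called between genotypes, 583 remained among the 597 without a 0 h array. For the changed genotype difference, 15 genes passed with trend and robust settings and 0 to 6 when an array was left out; it could not be fitted without a 0 h array. The mean of all probe sets gave 295, 269, 351 and 306 genes 2-fold apart at 0, 1, 2 and 4 h. With an estimated correlation 0 lists passed between genotypes and 3, 2 and 2 after LPS, and fry called 16 at 4 h. Leaving out an array gave 6 to 7 lists between genotypes and 12 to 15, 11 and 10 to 11 after LPS. Other causes were not tested. Between 10016 and 12079 of 12540 genes lay above background per array, and differences below it could not be measured.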

Other observations

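The test of other array splits and that of a faster time course were chosen before their results were seen, the others after. The chance test of Il6 and the Sprr2 genes and the test of genes beside Zc3h12a each replaced 1 over a wider set of genes whose result had been seen.

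The NF-kB list had 4 of 19 members lower in the labelled-knockout arrays and 0 higher, with Cd83, a dendritic cell maturation marker, at -1.02 (SE 0.09) and the signalling adaptor gene Traf1 at -1.04 (SE 0.09). The list missed the threshold (camera adjusted p = 0.0508). It passed without either 0 h array (0.0181) and after cyclic loess (0.0341). Its adjusted p was up to 0.181 with other arrays left out and 0.575 with an estimated correlation. Of 33 interferon-stimulated genes 3 rose and 5 fell, with Oasl2 at -0.95 (SE 0.12) and the GTPase gene Iigp1 at 1.90 (SE 0.34). The Iigp1 call was lost without either 0 h or 2 h array, at adjusted p up to 0.0832, and with trend and robust settings (0.0760). The lipoxygenase genes Alox15 and Alox5, of the eicosanoid list, were higher by 2.88 and 1.45. That list missed the threshold (adjusted p = 0.0919) and passed without either 4 h array (0.0153). The eicosanoid list's adjusted p was up to 0.285 with other arrays left out, 0.122 after cyclic loess and 0.630 with an estimated correlation. Cish, an inhibitor of cytokine signalling, was higher by 1.67 (SE 0.22).

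Of 9 neutrophil markers 4 rose and 2 fell. S100a9 rose by 3.12 (SE 0.11) and Mmp8 by 1.62 (SE 0.12), and Mmp9 fell by 1.68 on the log2 scale, while S100a8, chosen after its value was seen, differed by 0.12. The list missed the threshold (adjusted p = 0.0508) and passed without either 0 h array (0.0359) or either 2 h array (0.0408). The neutrophil list's adjusted p was up to 0.110 with other arrays left out, 0.117 after cyclic loess and 0.575 with an estimated correlation. Of 7 mast cell markers 2 fell and of 9 T and NK cell markers 2 rose (list adjusted p = 0.422 and 0.0919).

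The genotype count of 1690 was set against other splits of the 8 arrays into 4 and 4. Of 35 splits 32 could be fitted with time as a block, and 1 of the 32, the real one, gave as many genes. The highest of the others gave 0. In every other split a true genotype difference adds to the residual spread and lowers the count, so the bound of 5% of fitted splits set beforehand was not a fair one. Only 8 splits part all 4 time pairs as the real one does, too few for a share under 0.05.

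The resident macrophage and alternative activation genes differed at every time, LPS or not. The explanation examined was a lower share of macrophages that raised the markers of all other cell types. The mesothelial and stromal median of -1.04 (SD of members 0.65), already seen, goes against a rise in all of them. A lower share need not raise every other cell type, so this list cannot exclude it. Other lists went both ways, with medians of -0.39 for B cell (Ighm included), -0.28 for mast cell, -0.11 for dendritic cell, 0.56 for neutrophil and 0.16 for T and NK cell markers. General macrophage markers had a median of -0.10 and missed the threshold. A change in the macrophage share is therefore not decided. That the resident macrophage and alternative activation genes were carried along beside Zc3h12a is argued against by position alone, not by the expression values. Of the 19 called members of both lists, 0 lie among the 100 measured genes nearest to Zc3h12a and 0 on its chromosome. Of those 100 genes 13% passed the threshold, against 13.5% of all genes. More resident macrophages in the labelled-knockout cells may account for the resident macrophage part of the pattern and stay open. Of that list, whose values had been seen, 9 of 10 markers were higher at all 4 times. Whether more resident macrophages would also raise the alternative activation genes was not tested. A change within the same cells, an effect of carried genes on others and a difference between the mice used were not tested.

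Il6 and the Sprr2 genes were higher in the labelled-knockout arrays after LPS. A generally faster response is argued against by the advance at 1 h. This is the change from 0 to 1 h in labelled knockout minus that in wild type, as a share of the wild-type change from 1 to 2 h. Over 1049 genes that changed at least 2-fold in that hour, its median was 0.0384 (95% of 2000 resamples of genes 0.0234 to 0.0543). It was 0.0685 for the 435 rising and 0.0235 for the 614 falling genes, against 1.49 for Il6, whose wild-type 0 h reading lay below background. The interval is a spread over genes of single arrays, not between replicates, and the wild-type 1 h array enters both parts of the share. Chance among 8 arrays could remain for these genes, which were picked for their size: for a changed difference the smallest adjusted p of Il6, Sprr2d and Sprr2f was 0.9996, with unadjusted p of 0.0933, 0.00031 and 0.0050. The Sprr2d and Sprr2f differences after LPS were 4.52 or more, against an SD over all genes of 0.47 to 0.52 at single times, which is no spread between replicates, and both passed without either 1 h array (adjusted p = 0.00122 for each; 0.00122 to 0.99995 over 13 alternatives for Sprr2d). A lasting effect of Zc3h12a loss on these mRNAs was not tested.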
